A study of Mus musculus with 14 samples.

How the data were processed

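RNA was sequenced from 14 mouse samples with 1 library in each group: 3T3-L1 and immortalized brown preadipocytes at 0h, 1h, 2h, 4h, day 2 and day 7 of adipogenesis, and brown adipose tissue of adult mice and of embryos. Per the labels' protocols, cells were plated 4 days ahead, and confluent cultures received insulin (0.02 µM), the thyroid hormone T3 (1 nM), IBMX, a phosphodiesterase inhibitor that raises cAMP (0.5 mM), dexamethasone, a synthetic glucocorticoid (1 µM), and indomethacin (0.125 mM). The labels give the same growth and induction text for all samples, tissues included, and describe only the brown line's origin, so the conditions of 3T3-L1 are uncertain. RNA was taken up in Trizol, messenger RNA was purified on Dynabeads and libraries followed the standard Illumina protocol, per the labels. The labels mark the brown day 2 and day 7 libraries as duplicates of samples of another series. Groups came from the sample titles.

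The culture files hold RPKM values (reads divided by transcript length and by library size), made by the authors, per the file headers and names, and rounded to 2 decimals. The tissue files hold the read count and the RPKM of each transcript, both deposited by the authors, per the file headers. CASAVA 1.8.2 and the build mm9 are named in the submitters' processing notes with no role given. The aligner, the counting program, its filters and its use of strand are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart. Headers of the day 2 and day 7 culture files are styled differently from those of 0h to 4h in both lines, so a batch of late libraries is confounded with time.

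Each file lists the same 29082 RefSeq transcripts, of 22836 gene symbols. Of 49 symbols that had become numbers, 48 were recovered by accession from a RefSeq table of the GRCm38 assembly, which held 97.8% of the accessions, 90.0% of them under the same symbol. That table gave names, and the order of genes along this assembly for the neighbours of Mdm2; no coordinates are printed. Sequence words shared between transcripts came from the GENCODE transcripts of the same assembly, not of the submitters' build. For the 3906 genes with more than 1 transcript, 1 transcript was kept, and isoforms were not separated. Counts divided by RPKM in the tissue files gave transcript lengths, missing for 5320 transcripts. With these lengths, low RPKM values of the culture files were whole multiples of 1 read (100% of 138 to 302 values per library within 0.2 of a whole read), which gave the depth. Depth in M reads (M, mega) was 51.7, 54.3, 56.7, 48.6, 39.5 and 50.2 in 3T3-L1 from 0h to day 7 and 74.7, 39.8, 65.4, 43.0, 80.9 and 61.9 in the brown line. It was 5.35 in adult and 18.8 in embryonic tissue. A single read on a 2-kb transcript was worth 0.00618 to 0.0127 RPKM in culture.

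Because the culture values are RPKM and not counts, the test was limma (3.58.1, eBayes with trend) on log2(RPKM + 1), so fold changes of low genes are understated. Genes with an RPKM of at least 1 in at least 2 libraries were tested, 12428 in all. The model was additive in time and cell line over the 12 culture libraries. The replicate at each time is the cell line (n = 2), and the residual is the line by time interaction. Calls had a Benjamini-Hochberg adjusted p under 0.05 within each time. Library preparation, culture and cell line are not separated in this residual. 30 gene lists were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, adjusted over lists, and again with an estimated correlation and with fry. Erythroid markers had 0 members tested in culture. Within a line and between tissues, with 1 library each, a gene counted as different at 2-fold or more with the higher RPKM at least 2, and list medians were set against 10000 random lists of the same size and matched mean expression. In ratios between the tissues a count of 0 was set to a floor of 3 reads. Some of these ratios are printed with 95% Poisson intervals of the deposited counts, and others without. These intervals cover counting error only.

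The design, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. Klf4, Egr2 and Pparg are always named. From each list up to 4 members are named, those with the largest fitted change past the threshold, or else the largest difference in the 2 lines. Outside the lists, the 10 largest rises and 10 largest falls past the threshold are named at each time, with the same direction in both lines and an RPKM of at least 5 in at least 1 library of each. Between lines, the 10 largest in each direction with an RPKM of at least 5 are named, plus up to 4 per list. Between tissues, the 12 largest in each direction with the higher RPKM at least 10 are named, plus up to 4 per list. Beside these, Sgk1, Cebpb and Dusp1 at 1h, Insig1 at 4h and the genes set beside each other in culture and tissue were chosen after their values were seen where the rule does not name them. Some genes that the rule names are not reported here.

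Alternatives were a pseudocount of 0.1, no filter on low values, an RPKM of at least 5, median-of-ratios and quantile scaling, no cell line term, no trend, leaving out each library in turn, and leaving out the brown day 2 and day 7 libraries. Those added after seeing the data were the 0h to 4h libraries alone, the mean over a gene's transcripts, a test of the line by time interaction, and edgeR (4.0.16) and DESeq2 (1.42.0) on reads recovered from the RPKM of 12318 genes. Those recovered reads are estimates and served only as a check. DESeq2 on the deposited counts was not run, since they cover 2 libraries of 1 per group. In data simulated for the day 7 comparison (12004 genes, 100 changed per fold size), limma recovered 46% of 2-fold and 92% of 4-fold changes with 5 false calls. The simulation gave each gene the same spread at all times and drew genes independently. In the real data early counts rose once late libraries were left out, so the 5 false calls are no guide to the day 7 calls. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.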

Results

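RNA sequencing was used to follow gene expression while preadipocytes became adipocytes in culture, and in brown fat itself. 3T3-L1, an immortalized white preadipocyte line, and brown preadipocytes immortalized with SV40 T antigen were sampled at 0h, when confluent, and at 1h, 2h, 4h, day 2 and day 7 after induction. The brown line came from the interscapular brown fat of newborn mice with floxed Pparg alleles, and the labels name no Cre recombinase. Brown adipose tissue was also taken from adult mice and from embryos. The title of the series names KLF4, Krox20 (the product of Egr2) and PPARγ, and the time courses show how these factors and other genes moved during adipogenesis. Each of the 14 groups held 1 library, so no value within a group has a replicate check. The tests over time took the 2 lines as replicates (n = 2 at each time). Their p-values rest on how far the changes of these 2 lines differed, pooled over all times. Depth was 39.5 to 80.9 M reads (M, mega) in the culture libraries, and the deposited read counts summed to 4.02 M in adult and 17.5 M in embryonic tissue.

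The 3 factors of the title followed separate courses. Klf4, a zinc finger factor known as an early activator of adipogenesis, stood at 11.4 and 8.40 RPKM in 3T3-L1 and the brown line at 0h, at 36.5 and 28.5 at 2h and at 1.71 and 1.49 at day 7. Egr2, an immediate early zinc finger factor, stood at 6.74 and 9.39 RPKM at 0h and 39.9 and 54.4 at 1h. Pparg, the nuclear receptor that directs adipocyte differentiation, went from 15.4 to 244 RPKM in 3T3-L1 and from 9.50 to 144 RPKM in the brown line by day 7. In limma, Klf4 rose at 2h by 1.62 ± 0.27 (log2 ± SE, adjusted p = 0.0427), fell at day 2 to 3.00 and 1.41 RPKM (adjusted p = 0.00508) and fell by 2.05 ± 0.27 at day 7 (adjusted p = 0.00112). Pparg rose by 2.12 ± 0.17 at day 2 (adjusted p = 0.000703) and by 3.84 ± 0.17 at day 7 (adjusted p = 4.19e-05). Egr2 passed at no time, with a log2 difference of 2.41 at 1h (SE 0.66, limma adjusted p = 0.995) and -0.93 at day 7. Adjusted over the list alone, 2 of the 3 factors rose at 1h and 1 at 2h. With 1 library left out the 2h difference of Klf4 stayed at 1.56 to 1.69, but its call often ended. Its limma adjusted p was 0.426 without 3T3-L1 0h, 0.0555 without 1h, 0.364 without 2h, 0.0625 without 4h and 0.0501 without day 2, and 0.191, 0.0548, 0.198 and 0.0619 without brown 0h, 1h, 2h and 4h. It was 0.0836 with no filter on low values and 0.287 with no cell line term. The day 2 fall of Klf4 had an adjusted p of 0.0524 in limma without brown 0h and 0.0550 with no cell line term, and the day 2 rise of Pparg 0.0514 with no cell line term.

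**Figure D1:**
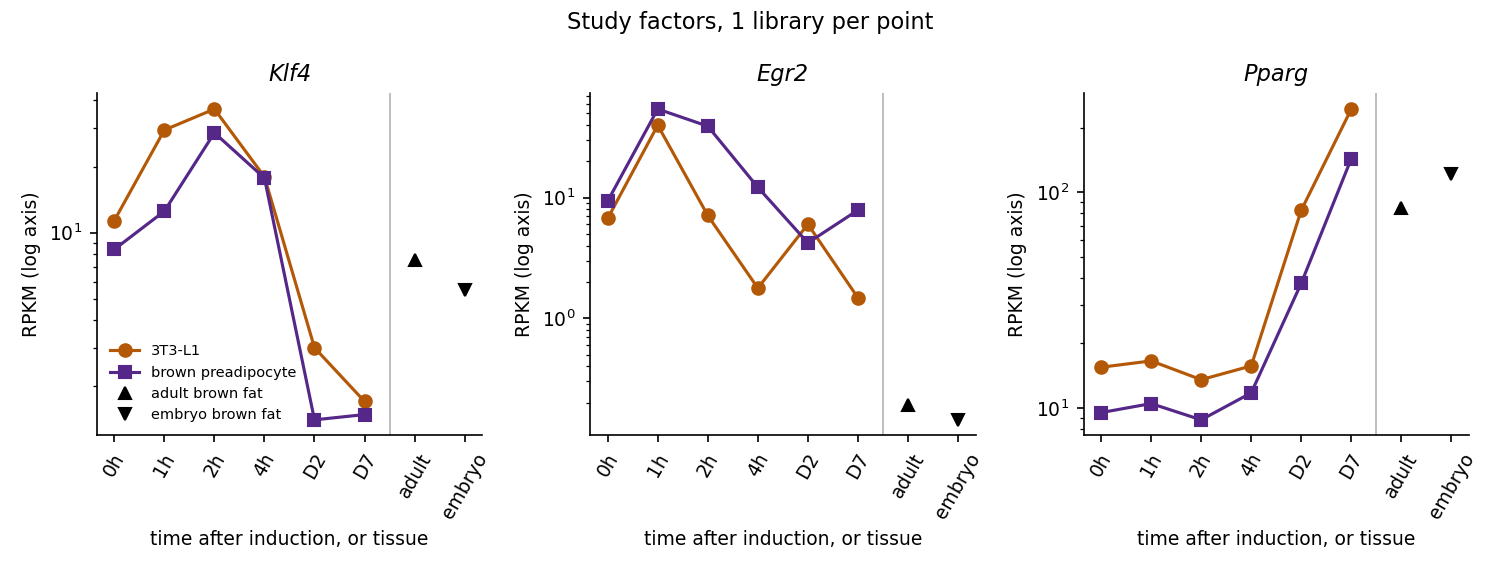
RPKM of Klf4, Egr2 and Pparg (vertical log axis) at 0h, 1h, 2h, 4h, day 2 and day 7 in 3T3-L1 and the brown line, with triangles for adult and embryonic brown fat; each point is 1 library. Egr2 is highest at 1h, Klf4 at 2h and Pparg at day 7 in both lines.

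At 1h, the genes that rose in both lines were early-response genes. Nr4a3 and Nr4a2, orphan nuclear receptors that cAMP induces, rose by 4.03 ± 0.32 and 2.94 ± 0.23, with Nr4a3 going from 1.14 to 45.8 RPKM in 3T3-L1 and from 0.60 to 18.5 RPKM in the brown line. Cxcl1, a neutrophil-attracting chemokine, rose by 3.85 ± 0.29 (11.0 to 183 and 3.98 to 66.6 RPKM). Id1, an inhibitor of basic helix-loop-helix factors, rose by 2.65 ± 0.23, and Rgs2, a regulator of G protein signalling, by 3.24 ± 0.34. These were the 5 genes past limma, with adjusted p from 0.00966 for Nr4a3 to 0.0391 for Rgs2, and 0 fell. Members that did not pass are given as values. Sgk1, a glucocorticoid-induced kinase, stood at 360.1 and 363 RPKM against 44.8 and 54.9 at 0h, Cebpb, an early adipogenic factor, at 468 and 220.2 against 130.2 and 49.0, and the phosphatase gene Dusp1 at 348 and 154 against 31.6 and 27.5. Of 27 immediate early genes tested, 2 rose, and 18 rose adjusted over the list alone (median log2 difference 2.21, camera adjusted p = 1.28e-86, adjusted p = 0.00791 with an estimated correlation). The cAMP-responsive list had 4 of 20 rise, or 10 adjusted over the list alone (median 0.79, camera adjusted p = 1.93e-55, adjusted p = 0.00174 with an estimated correlation). For inflammatory and secreted early genes it was 1 of 15, or 5 adjusted over the list alone (median 1.13, camera adjusted p = 5.72e-33, adjusted p = 0.00338 with an estimated correlation). Of 21 glucocorticoid-responsive genes, 0 passed limma over all genes and 6 rose adjusted over the list alone (median 0.67, camera adjusted p = 8.79e-27, adjusted p = 0.00322 with an estimated correlation).

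Other lists passed camera at 1h only with the preset correlation and had 0 members past limma over all genes. With an estimated correlation the adjusted p was 0.191 for adipogenic transcription factors (2 rose adjusted over the list alone), 0.105 for anti-adipogenic factors (1), 0.0650 for the KLF family (0) and 0.222 for circadian clock genes (2). It was 0.183 for preadipocyte and fibroblast genes, 0.651 for oxidative phosphorylation, 0.651 for interferon-stimulated genes and 0.664 for ribosomal protein genes, with 0 members adjusted over the list alone. Anti-adipogenic factors, fibroblast genes and oxidative phosphorylation had medians of -0.06, -0.01 and -0.02, against means of 0.32, 0.08 and 0.00291 and an upward camera result. With library rescaling the camera adjusted p was 0.115 for fibroblast genes and 0.180 for interferon-stimulated genes. At an unadjusted p under 0.05, limma counted 321 genes at 1h, where chance gives 621, and edgeR called 3 and DESeq2 77 on the reads recovered from the RPKM. A limma fit of the 0h to 4h libraries alone, chosen after the data were seen, called 24 rises and 0 falls. Leaving out 3T3-L1 0h or 1h gave 0 genes at 1h, 3T3-L1 4h 3 and 3T3-L1 day 2 8, and leaving out brown 0h gave 1, brown 4h 3 and brown day 2 8. All 5 calls ended without 3T3-L1 0h, 3T3-L1 1h or brown 0h, those of Rgs2 and Id1 also without brown 1h or either 4h library, and that of Rgs2 also without either 2h library. The calls of Rgs2 and Id1 also ended under quantile scaling.

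By 2h, 3 of 19 adipogenic transcription factors, Cebpd, Cebpb and Tle3, had risen, and 10 of 20 cAMP-responsive genes. Cebpd and Cebpb, early C/EBP factors, rose by 2.63 ± 0.34 (adjusted p = 0.0268) and 2.37 ± 0.42 (adjusted p = 0.0460) in limma, Cebpb from 130.2 to 484 RPKM in 3T3-L1 and from 49.0 to 358 RPKM in the brown line. Nr4a3 rose by 5.23 ± 0.32, Rgs2 by 4.07 ± 0.34, the clock gene Per1 by 2.58 ± 0.29 (12.2 to 49.5 and 6.76 to 71.3 RPKM) and Tle3, a corepressor that PPARγ also uses, by 1.29 ± 0.22. Outside the lists, the steepest rises were of Thbd (thrombomodulin), by 3.62 ± 0.42, and Vdr, the vitamin D receptor, by 3.47 ± 0.34 (12.8 to 201 and 8.98 to 82.3 RPKM), followed by 1810011O10Rik, Sphk1 (a sphingosine kinase), Dusp5, Sdc4, Dos, Vegfa (an angiogenic growth factor), Ugdh and Nipal1. Vegfa went from 32.5 to 181 RPKM in 3T3-L1 and from 46.1 to 235 RPKM in the brown line. Falls were led by Osr1, a mesenchymal zinc finger factor, which fell by 2.01 ± 0.30 (64.4 to 15.2 and 22.0 to 4.71 RPKM), Irs1, an insulin receptor substrate, by 1.93, and Bbc3, a pro-apoptotic gene, by 1.89, followed by Ahdc1, Sall2, Pcdh18, Nynrin, Mir3101, Prr12 and Patz1. Klf2, an anti-adipogenic KLF, did not pass at -2.22 (limma adjusted p = 0.0624).

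The cAMP-responsive list had 10 of 20 members rise at 2h, or 12 adjusted over the list alone (median 1.59, camera adjusted p = 2.76e-28, adjusted p = 0.00874 with an estimated correlation). Among glucocorticoid-responsive genes 3 of 21 rose, or 9 adjusted over the list alone (median 1.46, camera adjusted p = 1.05e-17, adjusted p = 0.00874 with an estimated correlation), and Errfi1, a feedback inhibitor of EGF receptor signalling, rose by 2.85 ± 0.42. Inflammatory genes, with Cxcl1 up by 2.65 and the cytokine Il6 up by 2.49, had 2 of 15 rise, or 8 adjusted over the list alone (median 1.42, camera adjusted p = 2.89e-14, adjusted p = 0.0249 with an estimated correlation). Of 27 immediate early genes 4 rose, Atf3 by 1.84 among them, and 9 adjusted over the list alone (median 1.16, camera adjusted p = 2.77e-20, adjusted p = 0.133 with an estimated correlation). H3K4 methyltransferases and cofactors had 2 of 13 fall, the coactivators Ncoa6 by 1.06 and Ep300 by 0.79, and 6 adjusted over the list alone (median -0.46, camera adjusted p = 0.000870, adjusted p = 0.339 with an estimated correlation). Adipogenic transcription factors had 3 of 19 rise and 0 fall over all genes, or 4 and 4 adjusted over the list alone, with a median of -0.24 and a mean of 0.21. The KLF family had 1 of 14 rise, or 3 rise and 3 fall adjusted over the list alone (adjusted p = 0.336 with an estimated correlation), and clock genes 1 of 17, or 4 and 2 adjusted over the list alone (adjusted p = 0.336 with an estimated correlation). Fibroblast genes (adjusted p = 0.115 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.536 with an estimated correlation; median 0.000568, mean -0.00156) and ribosomal protein genes (adjusted p = 0.630 with an estimated correlation) passed camera with the preset correlation and had 0 members past limma. With library rescaling the camera adjusted p was 0.285 for the KLF family and 0.0507 for clock genes.

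In all, 63 genes rose and 113 fell at 2h in limma. The median log2 difference of all genes was -0.17, and rescaling by the median of ratios, which brought it to 0, gave 61 rises and 31 falls; quantile scaling gave 58 and 29. After either rescaling the calls of Irs1, Mir3101, 1810011O10Rik, Sphk1 and Ep300 ended, those of Cebpb and Pcdh18 under quantile scaling and that of Ugdh under the median of ratios. With no filter on low values 10 genes rose and 4 fell, and with no cell line term 4 rose and 0 fell. Of 37 named results at 2h, 28 and 33 no longer passed under these settings. Fitted on the 0h to 4h libraries alone, 358 genes rose and 1737 fell, or 488 and 716 after rescaling. Without 3T3-L1 0h, 1h, 2h, 4h or day 7 the count was 0, 9, 3, 13 or 535 genes, and without the brown libraries of those times 4, 10, 0, 13 or 536.

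At 4h after induction, glucocorticoid-responsive genes, called as a list from 1h on, had 5 of 21 members past limma. Fkbp5, a chaperone partner of the glucocorticoid receptor, rose by 2.36 ± 0.39 (43.4 to 189.5 and 27.9 to 176 RPKM), Tsc22d3 (GILZ) by 2.27 ± 0.31 and Glul, glutamine synthetase, by 2.40 ± 0.43, while Nr3c1, the receptor itself, fell by 1.30 ± 0.16 (22.5 to 7.30 and 19.1 to 8.34 RPKM, limma adjusted p = 0.0160). Cebpd rose by 2.26 ± 0.34, Rgs2 by 4.09 ± 0.34 and Vgf, a cAMP-induced secreted protein, by 2.86 ± 0.19. Of the clock genes Per1 and Per2 rose by 2.18 and 1.81 and Dbp, a clock output factor, fell by 1.60 ± 0.22. Stat5b, an adipogenic signal transducer, fell by 1.09 ± 0.15 and Ncoa6 by 0.89. Outside the lists the largest rises were of Ramp3, a receptor-modifying protein, by 4.78 ± 0.75 (0.05 to 23.6 and 1.22 to 70.2 RPKM), and Vdr by 4.26 ± 0.34, followed by Thbd, Uap1, Ugdh, Ctla2a, Sphk1, Adamts9, Gfpt2 and 1810011O10Rik. Ugdh, which makes the UDP-glucuronate used for hyaluronan, went from 42.2 to 631 RPKM in 3T3-L1 and from 59.4 to 402 RPKM in the brown line. The largest falls were of Adamts5, an aggrecan-cleaving protease, by 3.44 ± 0.34 (33.4 to 1.69 and 33.6 to 2.76 RPKM), and of Adra1d, Mrgprf, Rab3il1, 5430435G22Rik, Bbc3, Irs1, Zfp521, Cdc42ep3 and Fzd2. Zfp521, an inhibitor of adipogenic commitment, fell by 1.86 ± 0.37.

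Glucocorticoid-responsive genes had 5 of 21 rise at 4h, or 8 adjusted over the list alone (median 1.54, camera adjusted p = 7.09e-11, adjusted p = 0.0272 with an estimated correlation). For the cAMP-responsive list the count was 9 of 20, or 10 adjusted over the list alone (median 1.51, camera adjusted p = 5.91e-13, adjusted p = 0.0272 with an estimated correlation). The cholesterol synthesis list had a median of -0.91 with 0 of 21 past limma over all genes, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.00427, adjusted p = 0.799 with an estimated correlation). Its regulator Insig1 stood at 8.67 and 24.2 RPKM against 44.7 and 41.8. Inflammatory genes (0 of 15; 5 adjusted over the list alone; adjusted p = 0.354 with an estimated correlation) and immediate early genes (2 of 27; 2 adjusted over the list alone; adjusted p = 0.799 with an estimated correlation) had medians of 0.57 and 0.05. Clock genes had 2 rise and 1 fall of 17, or 4 and 2 adjusted over the list alone (adjusted p = 0.719 with an estimated correlation). Fibroblast genes (adjusted p = 0.381 with an estimated correlation), oxidative phosphorylation (adjusted p = 0.799 with an estimated correlation) and ribosomal protein genes (adjusted p = 0.799 with an estimated correlation) had 0 members past limma. With library rescaling the camera adjusted p was 0.186 for immediate early, 0.181 for clock and 0.107 for fibroblast genes. Adipogenic transcription factors had 2 rise and 2 fall, or 3 and 5 adjusted over the list alone, the KLF family 0, or 2 and 5, and H3K4 genes 1 fall, or 2. Cell cycle genes had a median of -0.71 and 0 of 30 past limma by either adjustment, while 1 rose and 17 fell in the fit of the 0h to 4h libraries alone. That fit also had 1 of the 21 cholesterol synthesis genes rise and 11 fall.

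At 4h limma called 116 rises and 181 falls with a median log2 difference of all genes of -0.13, and 151 and 138 once rescaling had brought that median to -0.03; quantile scaling gave 149 and 137. The calls of Mrgprf and Zfp521 ended after rescaling. The 0h to 4h libraries alone gave 870 rises and 2570 falls, or 1422 and 1943 after rescaling. Without 3T3-L1 0h, 1h, 2h, 4h or day 7 the count was 0, 50, 36, 0 or 995 genes, and without the brown libraries of those times 0, 53, 36, 0 or 1002.

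At day 2, 15 of 26 mature adipocyte genes had risen, and single genes such as Ptgs2 and Acta2 had fallen. Cebpa, a C/EBP factor that sustains adipocyte identity, rose by 4.73 ± 0.39 in limma (2.04 to 44.9 and 3.16 to 194 RPKM, adjusted p = 0.000703). Adipoq (adiponectin) rose by 6.72 ± 0.75, the lipid droplet gene Cidec by 6.25 ± 1.09 and Fabp4, a fatty acid carrier, by 4.81 ± 1.00, the last from 108 to 561 RPKM in 3T3-L1 and from 19.8 to 3159 RPKM in the brown line. Ptgs2, the inducible cyclooxygenase, fell by 4.14 ± 0.45, Acta2, smooth muscle actin, by 4.90 ± 1.19, and Hmga2, a chromatin factor of growing mesenchyme, by 2.90 ± 0.42. Mature adipocyte genes had 15 of 26 rise, or 21 adjusted over the list alone (median 2.88, camera adjusted p = 1.61e-13, adjusted p = 0.165 with an estimated correlation). Adipogenic transcription factors had 9 of 19 rise, Cebpd and Nfia among them, or 10 adjusted over the list alone (median 1.51, camera adjusted p = 1.59e-08, adjusted p = 0.165 with an estimated correlation). Glucocorticoid-responsive genes had 7 of 21 rise, or 9 rise and 1 fall adjusted over the list alone (median 1.86, adjusted p = 0.165 with an estimated correlation), led by Glul at 202 and 159 RPKM and Zbtb16, a zinc finger repressor, with a rise of 3.73 ± 1.02.

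Metabolic lists held both rises and falls at day 2. Fatty acid oxidation and the TCA cycle had 9 of 31 rise, or 11 adjusted over the list alone (median 0.55, adjusted p = 0.165 with an estimated correlation), with Acadm, the medium-chain acyl-CoA dehydrogenase, up by 2.00 ± 0.14. Oxidative phosphorylation had 8 of 45 rise, or 11 adjusted over the list alone (median 0.34, adjusted p = 0.32 with an estimated correlation). Lipogenesis had 7 rise and 3 fall of 19, or 8 and 3 adjusted over the list alone (median 0.17). With the preset correlation its camera adjusted p was 0.0317 as deposited and 0.0574 after rescaling. It was 0.165 as deposited with an estimated correlation. Pcx, pyruvate carboxylase, rose by 3.36 ± 0.16. Cholesterol synthesis had 13 of 21 fall, or 16 adjusted over the list alone (median -1.43, camera adjusted p = 4.64e-07, adjusted p = 0.32 with an estimated correlation), Fdps, farnesyl diphosphate synthase, by 2.51 ± 0.41. Among white-associated genes 3 of 11 rose, or 4 adjusted over the list alone (adjusted p = 0.165 with an estimated correlation), with Agt, angiotensinogen, up by 5.65 ± 0.80. Brown and thermogenic genes were not called as a list, though 2 of 16 rose, the coactivator Ppargc1b by 2.55 ± 0.28 and Esrra by 0.77. Immediate early genes had 9 of 27 fall, or 10 adjusted over the list alone (median -1.30, adjusted p = 0.474 with an estimated correlation), Ctgf, a connective tissue growth factor, by 3.83. Interferon-stimulated genes had 3 of 16 fall by either adjustment (median -2.06, adjusted p = 0.531 with an estimated correlation). Anti-adipogenic factors had 1 rise and 4 fall of 17, or 1 and 5 adjusted over the list alone (adjusted p = 0.165 with an estimated correlation), and inflammatory genes 1 and 4 of 15, or 1 and 5 adjusted over the list alone (adjusted p = 0.32 with an estimated correlation).

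Lists that camera did not call at day 2 still held single changes. Preadipocyte and fibroblast genes had 3 rise and 10 fall of 31, or 5 and 14 adjusted over the list alone, with Tagln, an actin-binding protein, falling by 3.17 ± 0.26. In the KLF family, where 2 rose and 4 fell of 14, Klf6 fell by 2.13 ± 0.46 and Klf9, an adipogenic KLF, rose by 1.86 ± 0.50. The cAMP list had 6 rise and 3 fall of 20, clock genes 2 and 2 of 17, imprinted genes 1 and 2 of 15, H3K4 genes 1 and 1 of 13 and housekeeping controls 0 and 3 of 13, Actb by 1.34. Cell cycle, ribosomal protein and keratinocyte lists had 0 of 30, 25 and 5 past limma. Of the few muscle, macrophage and cartilage markers tested, 2 of 3, 1 of 4 and 1 of 3 fell, and 0 of 2 endothelial and 0 of 3 Schwann and neuronal markers passed. Outside the lists Serpina3n, an acute-phase protease inhibitor, rose most, by 5.72 ± 0.60, followed by C3, G0s2, Adamts15, Hp, Fam107a, Col15a1, Igfbp4, 2400009B08Rik and Fam83a. Spp1 (osteopontin) fell most, by 4.13 ± 0.59, followed by Anxa3, Il1rl1, Plk2, Cryab, Tpm1, Myl9, Ankrd1 and Epha2. In total 768 genes rose and 1426 fell, with a median difference of all genes of -0.06, and quantile scaling gave 1183 and 1260, with a median of 0.03. Calls of Hbegf, Gnas and Cxcl10 ended under quantile scaling, of Per2 and Dlk1 under the median of ratios and of Sc4mol, B2m and Gusb under both. The count was 498 without 3T3-L1 0h and 502 without brown 0h. Files of day 2 and day 7 carry differently styled headers from those of 0h to 4h in both lines, so a batch of late libraries cannot be told apart from time.

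At day 7 both lines expressed adipocyte genes at high levels. Adipoq rose by 10.59 ± 0.75 (0.14 to 4622 and 0.03 to 601 RPKM) and Cfd (adipsin) by 10.03 ± 0.75, which in the brown line was listed at 0 at 0h and stood at 432 RPKM at day 7. Scd1, stearoyl-CoA desaturase, rose by 5.36 ± 0.62 to 4514 and 2473 RPKM, and Klf15, an adipogenic KLF, by 5.02 ± 0.99 (limma adjusted p = 0.00615). Mature adipocyte genes had 25 of 26 rise by either adjustment (median 5.68, camera adjusted p = 1.73e-18, adjusted p = 0.0923 with an estimated correlation). Lipogenesis had 14 rise and 1 fall of 19 by either adjustment (median 2.68, camera adjusted p = 4.96e-07, adjusted p = 0.0504 with an estimated correlation), and Pcx rose by 4.59 ± 0.16. Adipogenic transcription factors had 12 of 19 rise, or 14 adjusted over the list alone (median 1.28, adjusted p = 0.0946 with an estimated correlation), with Cebpa up by 5.76 ± 0.39 and Nr1h3, the liver X receptor α, by 4.14 ± 0.33.

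Most genes of oxidative phosphorylation and of fatty acid oxidation and the TCA cycle rose as well. Oxidative phosphorylation had 35 of 45 rise, or 39 rise and 1 fall adjusted over the list alone (median 1.06, camera adjusted p = 1.73e-18, adjusted p = 0.0946 with an estimated correlation), with the complex I subunit Ndufb9 up by 1.97 ± 0.13. Fatty acid oxidation and the TCA cycle had 28 rise and 1 fall of 31 (median 1.45, camera adjusted p = 1.14e-17, adjusted p = 0.0724 with an estimated correlation). The member that fell was Cpt1a, the liver form of carnitine palmitoyltransferase, by 2.45 ± 0.74. Brown and thermogenic genes had 7 of 16 rise by either adjustment (median 1.02, adjusted p = 0.0724 with an estimated correlation), among them Cox7a1 by 4.08 ± 0.46, Kcnk3 by 4.59 and Cox8b by 3.43. White-associated genes had 6 of 11 rise (adjusted p = 0.0923 with an estimated correlation), clock genes 8 rise and 2 fall of 17 (adjusted p = 0.156 with an estimated correlation) and glucocorticoid-responsive genes 6 and 1 of 21 (adjusted p = 0.108 with an estimated correlation).

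Many preadipocyte, fibroblast and ribosomal protein genes fell at day 7. Preadipocyte and fibroblast genes had 1 rise and 18 fall of 31, or 2 and 23 adjusted over the list alone (median -1.76, adjusted p = 0.0946 with an estimated correlation), with Thy1, a mesenchymal surface marker, falling by 3.57. Ribosomal protein genes had 14 of 25 fall, or 16 adjusted over the list alone (median -0.80, adjusted p = 0.655 with an estimated correlation), Rpl4 by 1.03, or by 0.83 after rescaling. Cell cycle genes had 7 of 30 fall over all genes and 0 adjusted over the list alone (median -1.38, adjusted p = 0.711 with an estimated correlation). Plk1, a mitotic kinase, fell by 1.99 ± 0.58 (15.7 to 0.90 and 41.3 to 22.6 RPKM). The cell cycle median was -2.79 within 3T3-L1 and only -0.20 within the brown line. Interferon-stimulated genes had 7 of 16 fall (median -1.67, adjusted p = 0.711 with an estimated correlation). Their median was -2.79 within 3T3-L1 and -0.54 within the brown line. Of immediate early genes 10 of 27 fell (adjusted p = 0.711 with an estimated correlation). For cholesterol synthesis it was 8 of 21, or 10 adjusted over the list alone (adjusted p = 0.711 with an estimated correlation). Anti-adipogenic factors had 2 rise and 6 fall of 17 and inflammatory genes 1 and 7 of 15. With the preset correlation camera called these lists only after rescaling (adjusted p = 0.0466 and 0.0220, against 0.106 and 0.0832 as deposited). With an estimated correlation the camera adjusted p as deposited was 0.313 and 0.494. Not called were the KLF family with 3 rises and 3 falls, the cAMP list with 5 and 3, imprinted genes with 1 and 4, H3K4 genes with 1 and 2 and keratinocyte markers with 1 rise of 5. Housekeeping controls had 1 rise and 4 falls: Sdha rose by 1.44 while Actb, Gusb and Ywhaz fell by 2.06, 1.47 and 0.76, and after rescaling the values were 1.64, -1.86, -1.27 and -0.57.

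Outside the lists the largest day 7 rises were of C3, complement component 3, by 7.79 ± 0.64, and G0s2, an inhibitor of triglyceride lipase, by 7.68 ± 0.33, followed by Apoc1, Mrap, Lgals12, Car3, Hp, A530016L24Rik and 2610528A11Rik. Spp1 fell most, by 5.40 ± 0.59, followed by Ccnd1 (cyclin D1) by 4.30, Plk2, Dpysl3, Anxa3, Slc38a4, Il1rl1, Bcat1 and Tpm1. Of 2 endothelial markers 1 rose, of 4 macrophage markers 1 rose and 1 fell, 2 of 3 muscle and 1 of 3 cartilage markers fell, and 0 of 3 Schwann and neuronal markers passed. In all 1849 genes rose and 3202 fell in limma with a median log2 difference of all genes of -0.19, and 2461 rose and 2381 fell relative to that shift, once rescaling had brought the median to -0.02; quantile scaling gave 2413 and 2580. Calls that ended were those of Klf6, Ifit1, Ifit2, Mvd and Fdps under the median of ratios, of Pck1 under quantile scaling and of Bub1, Mcm2, Mcm4, Mll1, Rps14 and Rpl19 under both. Without 3T3-L1 0h the count was 2900 and without brown 0h 2631.

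**Figure D2:**
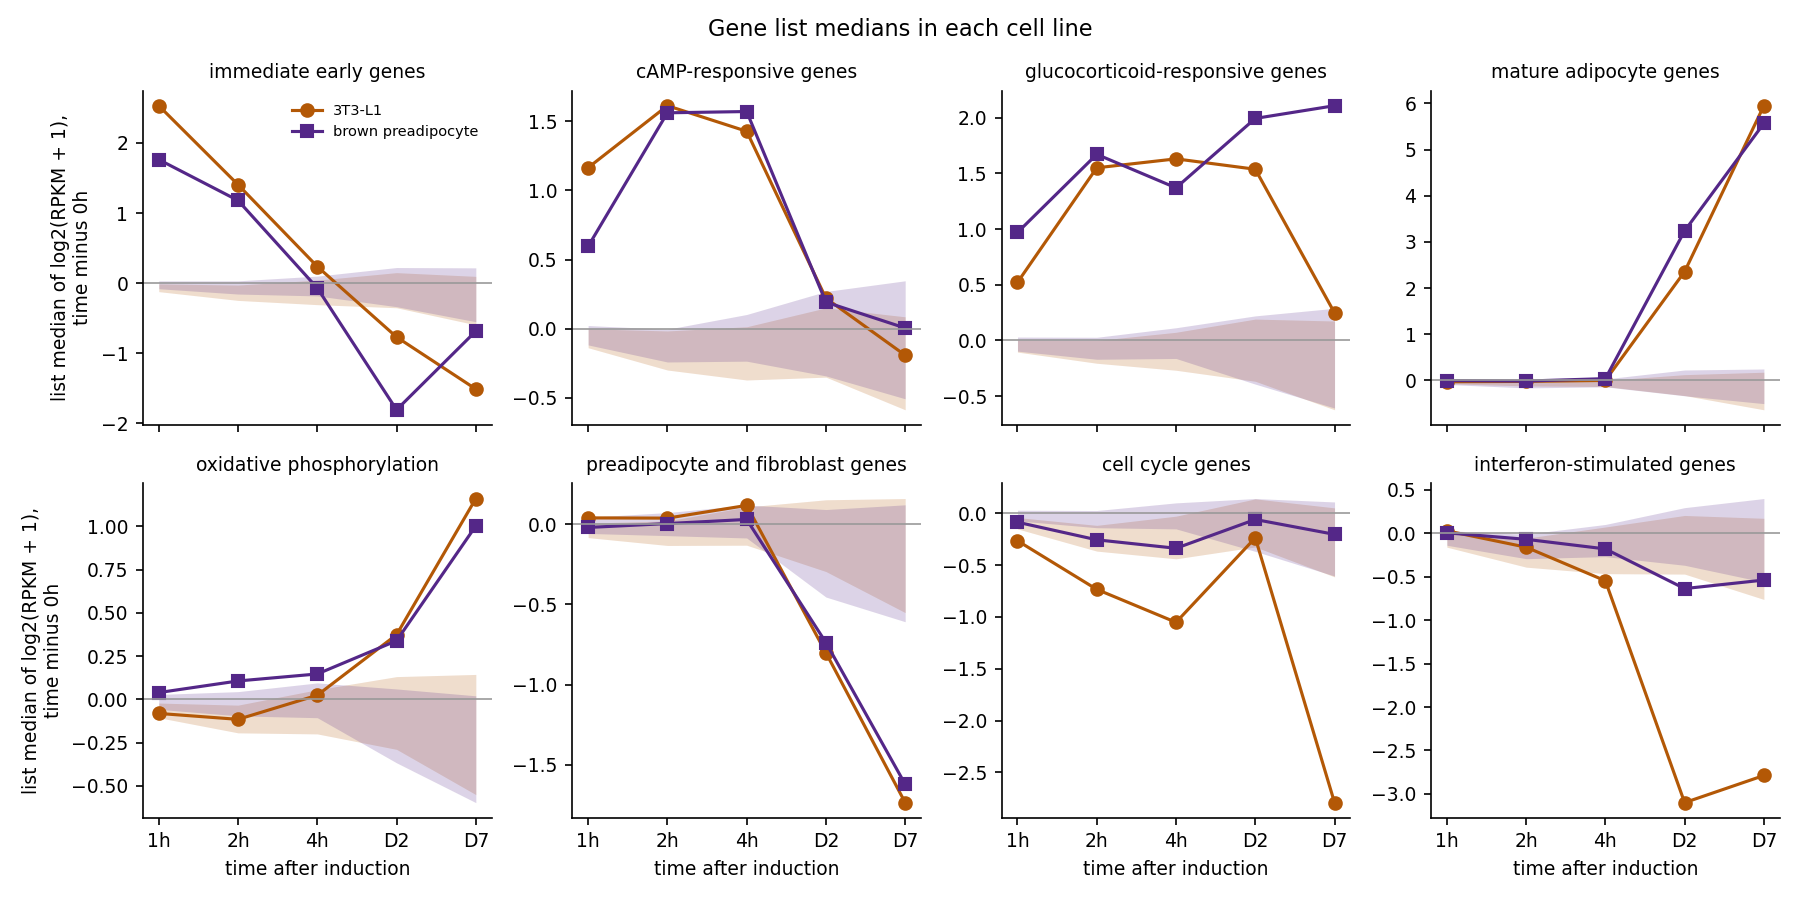
Median log2(RPKM + 1) difference from 0h of 8 gene lists (vertical axis, log2 units) at 1h, 2h, 4h, day 2 and day 7 in 3T3-L1 and the brown line, 1 library per point, with the middle 95% of 10000 random lists of matched expression shaded. Mature adipocyte genes reach 5.95 in 3T3-L1 and 5.57 in the brown line at day 7, and cell cycle genes -2.79 and -0.20.

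Interferon-stimulated genes changed differently from early to late times in the 2 lines, with 11 of 16 past a limma test of that difference (camera adjusted p = 0.0320 with an estimated correlation). The test was chosen after the values were seen. It took the early times and the late times of a line as replicates, so it has no replicate of a line at a time. In that test 0 of 30 cell cycle and 0 of 27 immediate early genes passed, and of 26 mature adipocyte genes 2 passed in each direction (camera adjusted p = 0.998 for each list with an estimated correlation). Because the test pools 0h to 4h, and day 2 with day 7, a change at 1h or day 7 alone widens its residual. It therefore cannot show that those lists moved alike in the 2 lines. Within a line there is 1 library per time, so the values that follow have no test. The immediate early list had medians of 2.53 in 3T3-L1 and 1.76 in the brown line at 1h, -0.77 and -1.80 at day 2 and -1.51 and -0.68 at day 7, and the cAMP list 1.61 and 1.56 at 2h. Mature adipocyte genes reached 5.95 and 5.57 at day 7, with 26 and 25 of 26 at least 2-fold higher than at 0h. Cell cycle genes had medians of -1.05 and -0.34 at 4h and -2.79 and -0.20 at day 7, when 28 and 1 of 30 were at least 2-fold lower. Interferon-stimulated genes stood at -3.10 and -0.64 at day 2, with 16 and 5 of 16 at least 2-fold lower. Cholesterol synthesis had a median of -1.37 and -0.34 at 4h, and -1.45 and -1.46 at day 2. Across genes, which are not independent replicates, the log2 differences of the lines had a Pearson r of 0.628 at 1h, 0.760 at 2h, 0.681 at 4h, 0.568 at day 2 and 0.704 at day 7 (Spearman rho 0.293, 0.712, 0.659, 0.555 and 0.651). The 0h libraries are separate, so no control is shared. Of 64, 271, 296, 962 and 1970 genes at least 2-fold different in both lines, 64, 267, 292, 922 and 1931 went the same way. At day 7, 828 were higher and 1103 lower in both, where independent lists would share 152 and 358. Within 3T3-L1 291 genes were higher and 493 lower at 2h (417 and 229 rescaled), 419 and 828 at 4h (580 and 470 rescaled) and 1248 and 2173 at day 7 (1627 and 1549 rescaled). For the brown line the counts were 217 and 155 at 2h (263 and 91 rescaled), 264 and 199 at 4h and 1547 and 1872 at day 7 (1743 and 1595 rescaled), and counting noise alone gave 0 to 5.

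Between the lines, over all 6 times, 27 of 30 cell cycle genes were higher in the brown cells, and Mdm2 was higher in the 3T3-L1 cells. Mdm2, the ubiquitin ligase that restrains p53, was lower in the brown line by a log2 difference of -4.76 (SE 0.10, limma adjusted p = 9.68e-07; 974 and 32.8 RPKM in 3T3-L1 and the brown line at 0h), as was its neighbour Slc35e3 (-4.76). Xist, the RNA of the inactive X chromosome, was higher in the brown line by 6.53 ± 0.15 (0.02 and 74.8 RPKM) and H19, an imprinted RNA, by 6.02 ± 0.48. Cell cycle genes had 27 of 30 higher in the brown line, or 29 adjusted over the list alone (median 1.78, camera adjusted p = 9.73e-07, adjusted p = 0.95 with an estimated correlation), and Mki67, a proliferation marker, was higher by 2.47 ± 0.49 (25.02 and 68.9 RPKM at 0h and 1.03 and 82.7 at day 7). Among brown and thermogenic genes 5 were higher and 2 lower of 16, with Lhx8, a brown-associated homeobox gene, higher by 3.28 ± 0.32 and listed at 0 in 3T3-L1, and Zic1, another, by 1.47 ± 0.29. The white-associated homeobox gene Hoxc8 was also higher in the brown line, by 3.58 ± 0.18. Ebf2, a brown commitment factor, was higher by 1.68 ± 0.27, and Zfp423, a factor that holds white identity, stood at -1.83. Dlk1, an imprinted inhibitor of adipogenesis, stood at -2.73, while the imprinted Cdkn1c, Grb10 and Meg3 were higher by 4.36, 4.50 and 4.49. Of the study factors, Egr2 was higher by 1.14 ± 0.38 (limma adjusted p = 0.0400), and Klf4 and Pparg stood at -0.46 and -0.68 (adjusted p = 0.0384 and 0.00128).

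The call of Egr2 between the lines ended under quantile scaling (limma adjusted p = 0.0537), with no filter on low values (0.0744) and without either library of 0h (0.0536), 2h (0.108), 4h (0.112) or day 7 (0.0854), and without 3T3-L1 1h (0.0538) or brown 1h (0.0539). With edgeR on recovered reads it had an adjusted p of 0.0686. That of Klf4 ended with no filter (limma adjusted p = 0.0624) and without 3T3-L1 0h (limma adjusted p = 0.0782), 1h (0.0835), 2h (0.0744) or day 2 (0.0890) and without brown 0h (0.0778), 1h (0.0819), 2h (0.0740) or day 2 (0.0885). Interferon-stimulated genes had 1 higher and 8 lower in the brown line of 16, or 1 and 9 adjusted over the list alone (median -1.07, camera adjusted p = 0.0350, adjusted p = 0.95 with an estimated correlation and 0.147 after rescaling). No other list was called by camera. Mature adipocyte genes had 1 higher and 5 lower of 26, oxidative phosphorylation 15 and 2 of 45, fatty acid oxidation 7 and 5 of 31, imprinted genes 7 and 4 of 15, H3K4 genes 7 and 1 of 13 and fibroblast genes 7 and 9 of 31. Adipogenic factors had 5 higher and 6 lower, anti-adipogenic factors 4 and 2, the KLF family 2 and 2 (0 adjusted over the list alone), immediate early genes 4 and 5, glucocorticoid-responsive 1 and 2, cAMP-responsive 4 and 5, inflammatory 2 and 3, clock 6 and 2, lipogenesis 3 and 2, cholesterol synthesis 3 and 2, white-associated 3 and 3, ribosomal protein 4 and 2 and housekeeping genes 7 and 1. Of the small lists, keratinocyte markers had 2 higher and 2 lower, muscle 2 and 0, endothelial 1 and 0, macrophage 0 and 1, Schwann and neuronal 2 and 0 and cartilage 0 and 1. Next in size after Mdm2 and Slc35e3 were Gas6, Ifi202b, Scara5, Clca1, Ptges, Fbxo2, Aspn and Cyp26b1, and other large differences in favour of the brown line were of Mir675, which lies within H19 and may share its reads (not tested), Crabp1, Sprr1a, Loxl2, Htra1, Hoxb9 and H1fx. In all 3889 genes were higher and 2314 lower in the brown line, or 3078 and 3295 under quantile scaling. Each line is 1 line, so the p-values compare these libraries.

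The adult and embryonic brown fat libraries both held thermogenic genes at high RPKM, and differed in lipogenic, muscle, proliferation and imprinted genes. With 1 library each there is no test, and the 95% Poisson intervals of ratios cover counting error only. Scd1 stood at 428 RPKM in the embryo and 10163 in the adult, 23.7-fold (95% interval 23.5 to 24.0) higher, and Fasn, fatty acid synthase, was 16.5-fold (95% interval 16.2 to 16.7) and Elovl6, a fatty acid elongase, 40.8-fold (95% interval 38.1 to 43.6) higher in the adult. The lipogenesis list had a median log2 difference of 1.31, above all of 10000 random lists of matched expression, with 13 of 20 members at least 2-fold higher in the adult and 2 in the embryo. Skeletal muscle markers had a median of 2.01 with 21 of 26 higher in the adult, where they took 1.06% of RPKM against 0.215%. They mark another cell type, and whether muscle was carried along with the tissue was not tested. Myh4, a fast myosin, stood at 0.177 and 155 RPKM, and Myh1 and Pvalb were 117-fold and 158-fold higher. Cell cycle genes had a median of -2.42, with 29 of 29 at least 2-fold higher in the embryo, and Mki67 was 153-fold (95% interval 65.5 to 471) higher there. Imprinted growth genes had a median of -2.89 with 13 of 16 higher in the embryo. Igf2, a fetal growth factor, was 71.0-fold (95% interval 57.6 to 88.6), Dlk1 237-fold (95% interval 138 to 445) and H19 39.5-fold (95% interval 35.4 to 44.1) higher in the embryo. Fibroblast genes had 22 of 30 higher in the embryo (median -1.89), with the collagen gene Col1a1 26.2-fold higher. Erythroid markers had 6 of 6 higher (median -3.30), although the globin genes have near-identical copies and their values are uncertain.

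Brown and thermogenic genes had a median of -0.49, close to the median of all genes, -0.56, with 5 higher in each direction of 24. Ucp1, the uncoupling protein of brown fat, stood at 1015 RPKM in the adult and 1194 in the embryo, Elovl3 was 12.7-fold (95% interval 10.3 to 15.7) higher in the adult and Cox7a1 3.46-fold (95% interval 3.18 to 3.77) higher in the embryo. Pparg stood at 84.7 and 122 RPKM (1.44-fold (95% interval 1.33 to 1.56) higher in the embryo) and Klf4 at 7.55 and 5.48 (1.38-fold (95% interval 1.11 to 1.70) higher in the adult). After rescaling Pparg was 1.03-fold and Klf4 2.05-fold higher in the adult, so the direction of Pparg turned, as did that of Ucp1, 1.27-fold higher in the adult. Egr2 stood at 0.189 and 0.144 RPKM, under the level considered. The clock list had a median of 0.33, with 4 of 16 at least 2-fold higher in the adult, Dbp (5.76-fold) and Nr1d1 (5.54-fold) among them, and 4 in the embryo. The other medians were 0.26 for cAMP-responsive, -0.08 for KLF, -0.11 for cholesterol synthesis, -0.31 for anti-adipogenic, -0.34 for macrophage, -0.37 for mature adipocyte, -0.47 for housekeeping, -0.49 for adipogenic transcription factor and -0.55 for fatty acid oxidation genes. They were -0.56 for immediate early, -0.59 for H3K4, -0.68 for glucocorticoid-responsive, -0.78 for 4 inflammatory, -0.95 for oxidative phosphorylation, -1.16 for endothelial, -1.23 for interferon-stimulated, -1.27 for white-associated and -2.12 for ribosomal protein genes, and 1.25 for 3 Schwann and neuronal markers, with 0 keratinocyte or cartilage markers high enough to count. Macrophage and immune markers went both ways, with H2-Aa, a class II antigen-presenting molecule, 22.4-fold higher in the adult.

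Among the largest differences of all genes, members of lists included, the adult was higher for Hsd11b1, an enzyme that regenerates active glucocorticoid (78.9-fold (95% interval 54.1 to 119.8)). It was also higher for Aspg (59.2-fold), H2-Q10 (46.6-fold) and Fabp3, a fatty acid carrier of the brown and thermogenic list (38.6-fold). In the embryo Adam11 was 335-fold and Mest, an imprinted gene, 203-fold (95% interval 128 to 342) higher, and Myh8, the perinatal myosin, with 2 adult reads, was 549.9-fold (95% interval 152 to 4542) higher. In all 537 genes were at least 2-fold higher in the adult and 2901 in the embryo, where counting noise gave 60. Relative to the median of all genes, -0.56, rescaling gave 1038 and 1203, and the list medians became 1.88 for lipogenesis, 2.54 for muscle, -2.05 for cell cycle, -2.36 for imprinted, 0.07 for brown and thermogenic and -0.38 for oxidative phosphorylation genes. Medians of the KLF, cholesterol synthesis, anti-adipogenic, macrophage, mature adipocyte, housekeeping, adipogenic transcription factor and fatty acid oxidation lists, below 0 as deposited, lay above 0 after rescaling. The adult library held 5.35 M reads by its RPKM, against 18.8 M for the embryo, so 1 read on a 2-kb transcript was worth 0.0935 and 0.0266 RPKM.

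**Figure D3:**
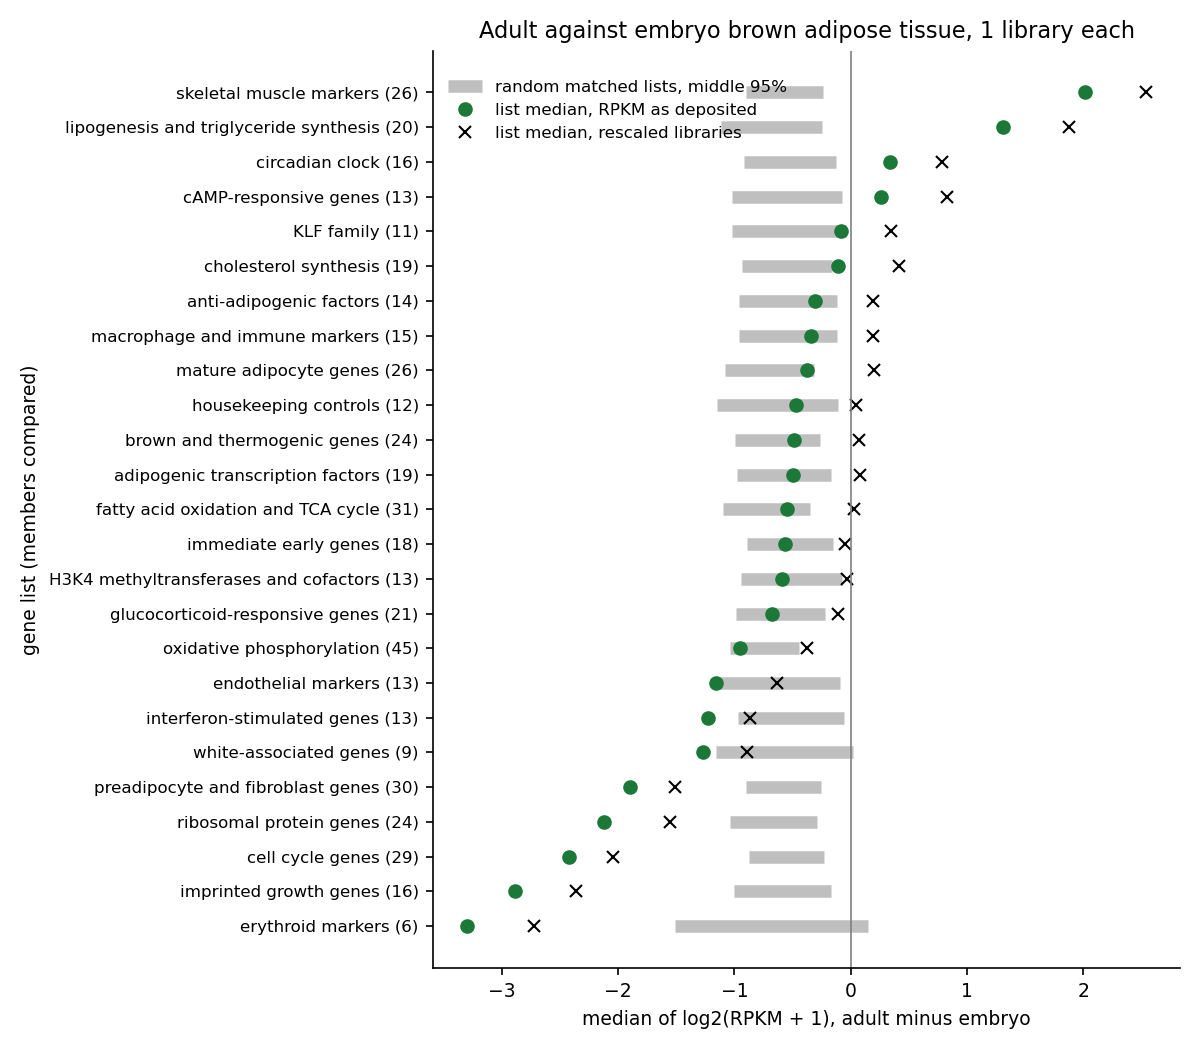
Median log2(RPKM + 1) difference, adult minus embryonic brown fat (horizontal axis, log2 units), for each gene list, 1 library per stage, as deposited (dots) and after median-of-ratios rescaling (crosses), with grey bars for the middle 95% of random lists of matched expression. Skeletal muscle markers and lipogenesis lie at 2.01 and 1.31, and imprinted growth and erythroid genes at -2.89 and -3.30.

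Set beside the tissues, the day 7 cultures had Fabp4, Adipoq and Pparg at high RPKM, and Ucp1, Cidea and Ppara at far lower RPKM than brown fat. Fabp4 stood at 4006 and 2801 RPKM in 3T3-L1 and the brown line at day 7, against 5959.9 in adult and 10168 in embryonic brown fat. Adipoq stood at 4622 and 601 against 554 and 826, and Pparg at 244 and 144 against 84.7 and 122. Ucp1 was listed at 0 in 3T3-L1 and 1.07 RPKM in the brown line, against 1015 and 1194 in the tissues. Cidea, a lipid droplet gene abundant in brown fat, stood at 2.98 and 6.65 against 1164 and 1676. Ppara, a receptor of fatty acid oxidation, stood at 0.43 and 6.99 against 70.3 and 107, and Prdm16, a brown fate factor, at 0 and 1.95 against 2.95 and 6.46. Of the markers of other cell types, Cdh5, of endothelium, was listed at 0 in both cultures and stood at 51.4 and 112 RPKM, and Ckm, of muscle, stood at 0 and 0.02 against 237 and 64.3. These levels come from libraries of different depth that were not rescaled to each other.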

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

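The line by time interaction, the interferon tests, the p53 test and the count of other splits were chosen after the results they bear on were seen; the tests of the Mdm2 neighbours and of shared sequence words were written before their results.

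The change from early (0h to 4h) to late (day 2 and day 7) libraries differed between the lines for 553 genes in limma, 262 with the brown change higher and 291 lower. Of these, 275 moved in opposite directions. With 1 library per line and time, this fit took the early times and the late times of a line as replicates. Its p-values measure the spread between times of 1 line, not between cultures. Each value here is the brown change minus the 3T3-L1 change in log2 units. Among inflammatory and interferon genes the difference was 3.40 for Ccl2, 2.63 for Ccl7, 3.65 for Cxcl5, -1.81 for Il1rn, 3.57 for Ifi44, 3.69 for Ifit1, 3.27 for Ifit3, 2.44 for Irf7, 3.33 for Isg15, 2.63 for Mx2, 4.11 for Oasl2, 2.00 for Stat2 and 1.51 for Usp18. For adipocyte and metabolic genes it was 1.83 for Acadl, 4.16 for Cd36, 3.60 for Lpl, 1.45 for Ebf2 and 3.21 for Zbtb16. Further values were 3.85 for Acta2, 1.83 for Myl9, -2.18 for Cd34, -2.49 for Thy1 and -3.36 for Ccnd1. There were also -1.44 for Grb10, -1.51 for Meg3, -1.95 for Ndn, -2.11 for Nnat, -2.09 for Hoxb9, -1.62 for Zic1, -1.49 for Wnt10b and 0.80 for Xist. The remaining values were -5.98 for Crabp1, 3.45 for Cyp26b1, -2.51 for Fam83a, -2.37 for Lor and -6.15 for Sprr1a. By list, camera also passed cholesterol synthesis (brown change lower, adjusted p = 0.000141), cell cycle (higher, 0.00995), oxidative phosphorylation (lower, 0.0208) and keratinocyte markers (lower, 0.0312), and with an estimated correlation none of these passed (adjusted p = 0.998, 0.998, 0.998 and 0.283). Klf4, Egr2 and Pparg did not pass this test, at 0.05, -0.65 and -0.38 (limma adjusted p = 0.980, 0.866 and 0.842).

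Interferon-stimulated genes dropped in the late 3T3-L1 libraries and less in the brown line, with a median difference of 2.47 and 11 of 16 genes past the interaction test (camera adjusted p = 1.00e-18, adjusted p = 0.0320 with an estimated correlation). Library scaling and compression of low brown values by the pseudocount are argued against as the whole cause, since 12 of the 16 passed after rescaling and the median was 3.49 with a pseudocount of 0.1. The 3T3-L1 median was -0.55 at 4h, below the middle 95% of random matched lists (whose lower bound was -0.46), a small drop in 1 library before day 2. Over both lines camera did not call the list at 4h (adjusted p = 0.991, and 0.256 on the 0h to 4h libraries alone), so this drop does not decide on a late batch. Relative to all genes the 3T3-L1 median was -0.34 at 4h, -3.02 at day 2 and -2.55 at day 7, against -0.62 and -0.44 in the brown line at day 2 and day 7. For the larger late drop a batch of the late libraries cannot be told apart from time. A response to differentiation that is larger in 3T3-L1 than in the brown line may equally account for it, and was not tested.

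Mdm2 and its neighbour Slc35e3 were far higher in 3T3-L1 than in the brown line at all 6 times, and a gain of copies in 3T3-L1 or a loss of p53 activity in the brown line, which carries SV40 T antigen, could each give such a difference. A gain reaching past the pair and Cpm is argued against, since 0 of the 10 nearest tested genes were at least 2-fold higher in 3T3-L1 at all times. For Cpm, next to Mdm2 among the tested genes, the test says little, because its values lay near the floor. Cpm stood at 0.51 RPKM in 3T3-L1 and 0.08 in the brown line at 0h, 0.62 and 1.21 at 4h and 2.31 and 0.07 at day 7. The 17 other p53 target genes tested had a median difference of 0.35 (quartiles -0.11 to 0.64), with 1 at least 2-fold higher in 3T3-L1 and 1 lower. This argues against loss of p53 activity as the whole cause only if p53 acted on those genes in 3T3-L1, which was not tested. A gain limited to Mdm2 and Slc35e3, or to them and Cpm, and reads running from Mdm2 or Slc35e3 into the other stay open and untested.

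Some ribosomal protein and housekeeping genes, such as Rpl11 and Rps6 (mean RPKM in culture 4.91 and 6.79), were listed at far lower RPKM than others of their class such as Rpl8 (716), and reads shared with near-identical copies could lower them. Across 38 genes, which are not independent replicates, the share of 36-base words found in other transcripts had a Spearman rho of -0.32 with mean RPKM (permutation p = 0.0502 with 100000 resamples; Pearson r -0.34, permutation p = 0.0412). Rps18 and Rpl3 were lower in 3T3-L1, at 5.23 and 5.16 against 140.3 and 36.1 in the brown line. The rho leaves shared reads open, and no biological explanation was tested.

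For the comparison of the lines, the real division of the 12 libraries into 6 and 6 was set beside others drawn at random. These made 100 divisions with the real one, of which 98 could be fitted. Only 1, the real one, called as many genes: 6203, against at most 87 in the others. Because libraries are paired by time, all 32 divisions that part the 2 libraries of every time were then listed, a choice made after the first count was seen. Again 1, the real one, called as many, against at most 18 in the others. Under exchange of the libraries within a time this is 1 of 32, the lowest share the count can reach, and it does not exclude chance. The libraries of a line also come from 1 line followed over time. Where the lines differ, the other divisions hold that difference in their residual and call fewer genes for it, so the gap is no measure of its size.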

How the results depend on the processing

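The fits of the 0h to 4h libraries, the recovered-read tests by edgeR and DESeq2, and the mean over transcripts were chosen after the data were seen. No block by replicate number was possible because every group holds 1 library, and the replicate number 1 only names it; the cell line term of the model pairs the libraries across times, and its removal is given with the other settings. DESeq2 on the deposited tissue counts was not run. No called change of a named gene changed direction under any alternative: of their results, with those of the uncalled study factors, 7420 kept direction and side of the threshold, 1462 no longer passed, 3 newly passed and 9 changed sign. These 9 were never called, and the cause was not tested. Pparg at 2h (-0.14) stood at 0.0626 under median-of-ratios and 0.0618 under quantile scaling, at 0.0637 under the first on the 0h to 4h libraries, at 0.0909 with edgeR and at 0.0868 with DESeq2. With 1 library left out, Pparg at 4h (0.15) ranged from -0.0271 (without brown 4h) to 0.324 (without 3T3-L1 4h), Egr2 at 4h (-0.57) from -1.23 (without brown 4h) to 0.0995 (without 3T3-L1 4h), and Egr2 at day 2 (-0.57) from -1.51 (without 3T3-L1 day 2) to 0.372 (without brown day 2). The last was 0.324 without brown day 2 and day 7. Of the counts, 123 stayed within 1.5 times and 72 moved further, and of the correlations between lines 2 stayed within 0.005 and 8 moved further.

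The count of genes called at 1h (5) became 0 without a filter, 3 under quantile scaling, 0 without the cell line term, 40 without the brown day 2 and day 7 libraries, 24 on the 0h to 4h libraries, 13 on these after rescaling, 3 with edgeR and 77 with DESeq2. In the same order the 2h count (176) became 14, 87, 4, 2243, 2095, 1204, 77 and 812, with 92 under median-of-ratios scaling. At 4h (297) it became 130 without a filter, 2 without the line term, 3530 without the brown late libraries, 3440 and 3365 on the 0h to 4h libraries and 1451 with DESeq2. Day 2 (2194) gave 375 without the line term, 4416 without the brown late libraries and 3638 with DESeq2, and day 7 (5051) gave 2059 without the line term. Dropping the line term moves the difference between lines into the residual, and leaving out the late libraries removes their line by time differences from it, which shows the cause of those changes; for the others the cause was not tested. Leaving out 1 library at a time gave 0 to 8 genes at 1h, 0 to 536 at 2h, 0 to 1002 at 4h, 498 to 3271 at day 2, 2631 to 5367 at day 7 and 4850 to 6674 between the lines. A time left with 1 library then rests on the spread of the other times. Of the day 2 results of 89 named genes, 46 no longer passed without 3T3-L1 0h and 52 without brown 0h, and of those of 106 genes at day 7, 29 and 34.

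Lists called by camera numbered 12, 10, 9, 12 and 15 from 1h to day 7 and 2 between the lines, and 4, 3, 2, 0, 0 and 0 with an estimated correlation. Fry called 4, 4, 2, 11 and 14 from 1h to day 7; it asks whether a list's genes move, on balance, one way, and does not compare them with other genes. With a pseudocount of 0.1, genes at least 2-fold different went from 784 to 1203 in 3T3-L1 at 2h, and in the brown line from 86 to 130 at 1h, 372 to 574 at 2h and 463 to 714 at 4h, since a lower pseudocount widens the change of low genes. Between tissues 3438 became 2241 after rescaling, which takes out the shift of all genes. The correlation between lines at 1h, 2h and 4h was 0.534, 0.723 and 0.644 with that pseudocount, and at an RPKM of at least 5 it was 0.679, 0.790, 0.718, 0.601 and 0.731 from 1h to day 7. The interaction count of 553 was 571 after rescaling and 490 with a pseudocount of 0.1. Depth limits the adult library most, where a gene with no read at 2 kb lies under 3 reads of 0.0935 RPKM each.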

Other observations

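The genes in this part were chosen after their values were seen. With 1 library per tissue and no list of mast cell genes tested, these are values only. Tpsb2, a mast cell tryptase, was 41.7 RPKM in embryonic brown fat and 0.172 in the adult, Cma1, a chymase, 27.6 and 0, and Cpa3, a carboxypeptidase of mast cells, 23.0 and 0.264. Xist stood at 0.0140 RPKM in adult and 30.8 in embryonic tissue, and Ddx3y, a Y-linked gene, at 22.4 and 8.99. In culture Xist ranged from 72.9 to 145 RPKM in the brown line and from 0.02 to 0.06 in 3T3-L1.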
